A study of Homo sapiens with 16 samples.

How the data were processed

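Gene expression was measured by sequencing of poly-A selected RNA in 16 libraries of SH-SY5Y cells, 4 in each of the groups untreated 2D, untreated 3D, MPP-treated 2D and MPP-treated 3D. Groups and replicate numbers came from the sample titles. MPP was 1 mM for 48 h from day 13, and all cultures were differentiated for 15 days. Per the labels, 2D cells were detached with Accutase and 3D scaffolds were placed whole in tubes, both were frozen, RNA was extracted by column and libraries were made with a commercial mRNA kit used as its maker recommends and whose strandedness is not given in the sources used here.

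The deposited values are read counts per gene divided by 1 DESeq2 size factor per library, a signal that is never negative. Per the submitters' processing notes, CASAVA 1.8.2, FastQC, STAR, featureCounts and DESeq2 were used with build GRCh38.p13; settings and annotation are not given in the sources used here. Every value of a library was a whole multiple of a single step within a tolerance of 0.01 reads, for 100.0% of the values, so whole reads were recovered. Size factors recomputed with DESeq2 from these reads were 0.9987 to 1.0007 times those in the values. The table holds 19898 genes by symbol and Entrez number, each with at least 11 reads over the 16 libraries, so genes of fewer reads are not analysed here. Of these, 19827 matched a RefSeq table of GRCh38.p14, used only for names.

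Recovered reads came to 24589435 to 46359070 per library. No pair of libraries in a group was alike within sampling noise: over the 24 pairs, the chi-square per degree of freedom across genes was 6.58 or more. Counting intervals and floors are for counting error only, since reads without molecular identifiers are not independent molecules. A group with 0 reads of a gene was given a floor of 3 reads over its 4 libraries.

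The design fixed in advance set limma as the main test for values that are not raw counts. This choice was kept after whole reads were recovered. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1). It covered the 16984 genes with a value of 10 or more in at least 4 libraries. All 16 libraries entered 1 fit of the 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of low genes. The 5 comparisons were MPP against untreated in 2D and in 3D, 3D against 2D untreated and with MPP, and the difference of the MPP effects. Gene lists were tested with camera (limma) at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, and again with an estimated correlation. Called lists printed without the estimated-correlation result kept their call there, at camera adjusted p of 6.83e-04 to 0.0428. Camera compares a list with the other genes.

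The design, the alternatives and 28 gene lists were fixed before the data were examined: cholesterol synthesis genes, mitochondrially encoded genes, cell cycle genes, integrated stress response genes, endoplasmic reticulum chaperone genes, retinoic acid response genes, noradrenergic and sympathoadrenal genes, glycolysis genes, cytosolic ribosomal protein genes, p53 target and apoptosis genes, metallothionein genes, replication-dependent histone genes, heat shock genes, inflammation and interferon genes, Schwann cell and glia markers, NRF2 antioxidant genes, autophagy and lysosome genes, complex I nuclear genes, hypoxia-response genes, stem and progenitor markers, extracellular matrix and adhesion genes, tricarboxylic acid cycle genes, immediate early genes, mesenchymal neuroblastoma-state markers, dopamine neuron and catecholamine genes, other neurotransmitter types, familial Parkinson disease genes and mature neuron and synapse genes. Of their 602 symbols, 26 were not analysed here and 14 were matched through another name. List members at 0 reads in a whole group moved no list's median when set to their floor.

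Genes are named by a rule fixed in advance. Among genes with a mean of 50 or more over the 16 libraries, it takes the 6 highest and 6 lowest log2 changes among called genes whose 4 values in a group all lie on one side of the 4 of the other. For the difference of effects it takes the 3 highest and 3 lowest called genes. It adds, for the 5 lists of smallest camera p, the 2 members of smallest p in the list's direction, and in every comparison TH, SLC18A2, SLC6A3, MAP2 and MKI67. Genes that the rule takes and that are not reported here were left out without replacement. Unnamed loci and pseudogenes were passed over. Genes named outside the rule were chosen after their values were seen, and the text says so.

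Alternatives were equal library totals, quantile normalisation, pseudocounts of 0.5 and 5, no filter, a mean of 50 or more, robust empirical Bayes, array weights, only the groups compared, a 2-fold minimum, a replicate block, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, edgeR with the block, camera with an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were equal totals over nuclear genes, a correction for transcript GC content and length, and leaving out untreated 3D replicates 1 and 3. Reads were recovered and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

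The tests were run on simulated data for the MPP effect in 2D, with 16984 genes of which 200 were changed by known folds. At folds of 1.5, 2, 4 and 8, limma recovered 78%, 94%, 100% and 100%, edgeR 80%, 96%, 100% and 100% and DESeq2 82%, 98%, 100% and 100%. Unchanged genes made up 4.62% of the limma calls, 5.05% of the edgeR calls and 14.0% of the DESeq2 calls. Camera called the list planted with changed genes and 0 of 28 lists of unchanged genes. Simulated genes varied independently of each other, so the simulation does not test the preset correlation of camera. Recovery was split by fold and not by expression level, so it is not shown for genes just above the filter. The simulation changed 200 genes, whereas limma called 5866 for MPP in 2D. It therefore does not test recovery or false calls when so large a share of genes changes.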

Results

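RNA was sequenced from SH-SY5Y cells, a human neuroblastoma line that can be driven toward a neuron-like state, after 15 days of differentiation to dopamine-like neurons. The design addresses how the culture surroundings alter features of Parkinson's disease in these cells. The cells grew on flat dishes (2D) or in a silk-collagen scaffold (3D). Cultures were left untreated or were given 1 mM 1-methyl-4-phenylpyridinium (MPP), a toxin that enters catecholamine cells and inhibits complex I of the respiratory chain, for 48 h from day 13. Each of the 4 groups held 4 libraries, and whole reads were recovered from the deposited values. The untreated 3D libraries were the shallowest, with 24589435 to 34658873 reads, against 34643854 to 46359070 in untreated 2D, 30399672 to 41813620 in MPP-treated 2D and 36554574 to 38414859 in MPP-treated 3D. Values below are normalised read counts as mean ± SD over n = 4 libraries, and log2 changes with their standard error (SE) from limma, on the log2(value + 1) scale.

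On a principal component analysis of 16984 genes, the first component held 35.9% of the variance and parted 2D from 3D, and the second held 19.7% and parted MPP from untreated. Libraries of a group correlated across genes at r = 0.968 to 0.985, genes not being independent replicates. Untreated 3D replicate 3 lay apart from its group on the fourth component, at 56.4 against -29.6 to 4.32, and replicate 1 had the highest mitochondrial share. The labels do not say that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, whose source is not known. Cells in 2D were detached with Accutase before freezing and 3D scaffolds were not, so handling and culture differ together.

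**Figure D1:**
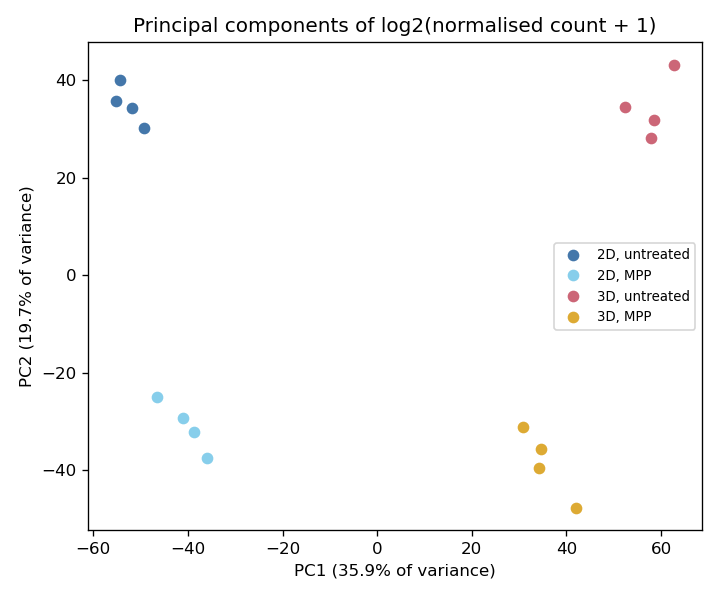
Each point is a library on the first (x) and second (y) principal component of log2(normalised count + 1), coloured by group. The 2D libraries lie at negative and the 3D libraries at positive values of the first component, which holds 35.9% of the variance, and the MPP libraries lie at negative values of the second, which holds 19.7%.

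The first comparison asked how gene expression in the scaffold differed from that on the dish without toxin. TH (Entrez gene 7054), the rate-limiting enzyme of dopamine synthesis, rose from 341 ± 25.8 in 2D to 5585 ± 823 in 3D (limma, log2 4.02, SE 0.11, adjusted p = 2.21e-18). SLC18A2 (Entrez gene 6571), the vesicular monoamine transporter of neurons, rose from 975 ± 76.6 to 3129 ± 173 (limma, log2 1.68, SE 0.089, adjusted p = 8.22e-13). SLC6A2, the noradrenaline transporter, fell from 2682 ± 90.9 to 126 ± 27.5 (limma, log2 -4.42, SE 0.15, adjusted p = 2.87e-16). MAP2 of the dendritic cytoskeleton and the proliferation marker MKI67 fell, with log2 changes of -0.39 and -1.24. The dopamine transporter SLC6A3 was not analysed here.

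Glycolysis and hypoxia-response genes were higher in untreated 3D. Of 17 glycolysis genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, median log2 1.13, camera adjusted p = 3.14e-15, adjusted p = 0.0253 with an estimated correlation). GPI rose from 7403 ± 420.2 to 39312 ± 4457 and ALDOA from 16549.7 ± 1418 to 63366 ± 3699.9. Of 21 hypoxia-response genes 18 rose and 0 fell (19 and 0 adjusted over the list alone, median log2 1.03, camera adjusted p = 2.14e-14). The angiogenic factor VEGFA rose from 4723 ± 277 to 38563 ± 5555 and the glucose transporter SLC2A1 from 1049.8 ± 61.8 to 4433 ± 338. Of 30 integrated stress response genes, targets of the ATF4 pathway that answers amino acid and translation stress, 24 rose and 2 fell (24 and 2 adjusted over the list alone, median log2 0.60, camera adjusted p = 9.04e-13). The amino acid transporter SLC7A5 rose from 4039 ± 228 to 24279 ± 261 and STC2 from 81.4 ± 12.4 to 2550.3 ± 187.

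Of 73 cytosolic ribosomal protein genes 67 rose and 0 fell in untreated 3D (67 and 0 adjusted over the list alone, median log2 0.56, camera adjusted p = 2.38e-18, adjusted p = 0.256 with an estimated correlation). RPL29 rose from 20221 ± 371 to 39125 ± 3229 and RPL3 from 28329.8 ± 1437 to 43469.7 ± 2602, though ribosomal protein genes have many pseudogene copies that can share their reads. All 30 cell cycle genes fell (30 adjusted over the list alone; median log2 -1.09, camera adjusted p = 3.14e-15, adjusted p = 0.215 with an estimated correlation). TOP2A fell from 9059 ± 586 to 4137 ± 163 and CENPF from 5567 ± 510.1 to 2006 ± 188. Of 24 mature neuron and synapse genes 3 rose and 18 fell (4 and 18 adjusted over the list alone, median log2 -0.45, camera adjusted p = 1.69e-05, adjusted p = 0.121 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; median log2 -1.21, camera adjusted p = 9.28e-08, adjusted p = 0.290 with an estimated correlation). Their share of reads was 9.62% ± 1.65 in untreated 2D and 4.47% ± 1.61 in untreated 3D, where replicate 1 held 6.84%.

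Several genes with no or almost no reads in untreated 2D were among those with the largest rises. FLT1, a VEGF receptor, had 0 reads in all 4 untreated 2D libraries and a mean of 1915 ± 297 in 3D, at least 2751-fold higher against a floor of 3 reads over the group. The mast cell tryptases TPSAB1 and TPSB2 also had 0 reads in 2D and were at least 2348-fold and 1990.2-fold higher; these near-identical paralogs can share reads. CBFA2T3, a transcriptional corepressor, had 2 reads in 2D and was 2167-fold higher in 3D, with a 95% exact Poisson interval of 599.9 to 17892 for counting error only. INSM1, a neuroendocrine transcription factor, rose from 1.18 ± 2.36 to 701 ± 54.5 and CAPN8 from 1.98 ± 3.31 to 790.4 ± 20.8. Besides SLC6A2, the lowest log2 changes by the fixed rule were in GABRP, TRHDE, the adhesion receptor CD44, ARHGAP42 and the innate immune receptor TLR7, with log2 changes from -5.11 for GABRP to -3.15 for TLR7.

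In all, 7830 of 16984 genes differed between untreated 3D and 2D by limma with Benjamini-Hochberg adjustment, 3932 higher and 3898 lower in 3D, and 2106 of them by at least 2-fold. The higher share of 50.2% became 38.3% with libraries scaled to equal nuclear totals. Camera called 9 of 28 lists, of which 3 held with an estimated correlation: glycolysis, hypoxia-response and integrated stress response genes.

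**Figure D2:**
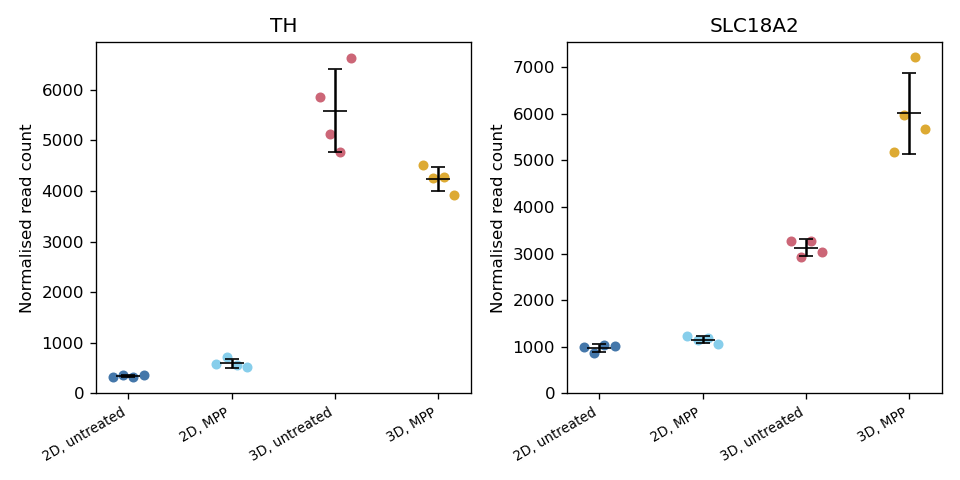
Points are the normalised read counts of TH and SLC18A2 in each library, by group, with the mean and SD (n = 4) in black. TH averaged 341 in untreated 2D and 5585 in untreated 3D, and SLC18A2 averaged 3129 in untreated 3D and 6007 in MPP-treated 3D.

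The next comparison asked what 48 h of MPP changed on the flat dish. All 13 mitochondrially encoded mRNAs, which code for respiratory chain subunits, fell (13 adjusted over the list alone, median log2 -3.54, camera adjusted p = 8.07e-28, adjusted p = 0.0301 with an estimated correlation). Cytochrome c oxidase subunit COX3 fell from 377963 ± 59583 to 11364 ± 1093 (limma, log2 -5.05, SE 0.15, adjusted p = 7.33e-17). Complex I subunit ND3 fell from 44146 ± 8155 to 918 ± 91.1 (limma, log2 -5.57, SE 0.13, adjusted p = 2.17e-18). The share of reads on the 13 mRNAs was 9.62% ± 1.65 in untreated 2D and 0.874% ± 0.0754 with MPP. COX2, CYTB, COX1 and the mitochondrial proline tRNA TRNP also fell, with log2 changes of -4.80, -4.55, -3.95 and -6.56. Without strand, TRNP reads cannot be told from transcripts of the other mitochondrial strand.

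Cholesterol synthesis genes rose with MPP in 2D. Of 22 members 21 rose and 1 fell (21 and 1 adjusted over the list alone, median log2 1.49, camera adjusted p = 2.17e-30). HMGCS1, an early enzyme of the pathway, rose from 7533 ± 277 to 44966 ± 2007 (limma, log2 2.58, SE 0.076, adjusted p = 7.33e-17). DHCR7, a late enzyme, rose from 5456 ± 162 to 23956 ± 1039.8. Of 30 integrated stress response genes 26 rose and 1 fell (27 and 1 adjusted over the list alone, median log2 1.09, camera adjusted p = 1.35e-25). Asparagine synthetase (ASNS) rose from 2272 ± 56.5 to 7080.2 ± 273 and SLC7A5 from 4039 ± 228 to 11625 ± 575. The cystine transporter SLC7A11 had the largest rise by the fixed rule, from 14.1 ± 16.7 to 385 ± 55.1 (limma, log2 5.20, SE 0.42, adjusted p = 3.13e-09), with 1 untreated library at 39.2. FUT3, LIPG, PRDM16, GOLGA6C and C6orf223 followed, with log2 changes from 4.52 for FUT3 to 3.32 for C6orf223. GOLGA6C belongs to a family of close copies that can share reads.

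All 30 cell cycle genes fell with MPP in 2D (30 adjusted over the list alone, median log2 -1.19, camera adjusted p = 1.52e-27, adjusted p = 0.0428 with an estimated correlation). MKI67 fell from 5993 ± 873 to 1761 ± 305, TPX2 from 2471 ± 268 to 1012 ± 124 and PCNA from 1875 ± 88.8 to 838 ± 31.1. Of 18 endoplasmic reticulum chaperone genes 3 rose and 14 fell (3 and 14 adjusted over the list alone, median log2 -0.48, camera adjusted p = 1.62e-05, adjusted p = 0.0776 with an estimated correlation). HSPA5 fell from 13647 ± 579.8 to 6702 ± 419 and CALR from 17228 ± 543 to 9795 ± 429. TH rose from 341 ± 25.8 to 595 ± 91.0 (limma, log2 0.79, SE 0.11, adjusted p = 5.27e-06). MAP2 was at 9984 ± 959 and 10226 ± 1719.6 and was not called (limma, adjusted p = 0.875).

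Further lists were called in 2D. Retinoic acid response genes: of 12, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median log2 0.46, camera adjusted p = 2.02e-05). Of 22 p53 target and apoptosis genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, median log2 0.24, camera adjusted p = 9.37e-04, adjusted p = 0.113 with an estimated correlation). Of 14 inflammation and interferon genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, median log2 0.30, camera adjusted p = 0.00907). Of 8 Schwann cell and glia markers 4 rose and 0 fell (5 and 0 adjusted over the list alone, median log2 0.85, camera adjusted p = 0.0259, adjusted p = 0.0800 with an estimated correlation). The call on Schwann cell markers was lost with equal library totals (0.0567) or among genes with a mean of 50 or more (0.0549), at an adjusted p of 0.0151 to 0.0800 over all camera alternatives. Of 73 cytosolic ribosomal protein genes 14 rose and 0 fell (12 and 0 adjusted over the list alone, median log2 0.16, camera adjusted p = 6.41e-04, adjusted p = 0.648 with an estimated correlation). Of 17 glycolysis genes 1 rose and 10 fell (1 and 10 adjusted over the list alone, median log2 -0.29, camera adjusted p = 1.11e-04, adjusted p = 0.188 with an estimated correlation). Of 15 noradrenergic and sympathoadrenal genes 1 rose and 7 fell (1 and 9 adjusted over the list alone, median log2 -0.21, camera adjusted p = 1.11e-04, adjusted p = 0.237 with an estimated correlation). Of 7 genes of the metallothionein list, which holds the zinc and copper binding metallothioneins and the zinc transporter SLC30A1, 0 rose and 6 fell (0 and 6 adjusted over the list alone, median log2 -0.77, camera adjusted p = 0.00231, adjusted p = 0.113 with an estimated correlation). SLC30A1, named here after its values were seen because it is not a metallothionein, was among those that fell (limma, log2 -0.63, SE 0.14, adjusted p = 0.00164). Of 7 replication-dependent histone genes 0 rose and 4 fell (0 and 4 adjusted over the list alone, median log2 -1.63, camera adjusted p = 0.00356, adjusted p = 0.0385 with an estimated correlation). The libraries were poly-A selected, and how far these reads follow all histone mRNA was not tested. Of 12 heat shock genes 1 rose and 8 fell (1 and 8 adjusted over the list alone, median log2 -0.27, camera adjusted p = 0.00356, adjusted p = 0.230 with an estimated correlation).

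MPP changed 5866 of 16984 genes in 2D by limma with Benjamini-Hochberg adjustment, 2998 upward and 2868 downward, and 1084 of them by at least 2-fold. The upward share of 51.1% became 70.3% with equal library totals, which moved the median of all genes to 0.12 on the log2 scale. Library totals include the mitochondrial mRNAs, whose share of reads fell from 9.62% to 0.874%. Equal totals therefore scale nuclear genes upward with MPP. Equal nuclear totals moved changes the other way, that of SLC18A2 from 0.24 to 0.20. The small rise in SLC18A2 (limma, log2 0.24, SE 0.089, adjusted p = 0.0390) was lost with edgeR (0.0510), without untreated 2D replicate 1 (0.0573), without untreated 2D replicate 2 (0.143), without untreated 2D replicate 4 (0.0515), without MPP-treated 2D replicate 1 (0.110), without MPP-treated 2D replicate 2 (0.0680), without MPP-treated 2D replicate 3 (0.0852) or with equal nuclear totals (0.110), at an adjusted p of 0.00319 to 0.143 over all alternatives.

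**Figure D3:**
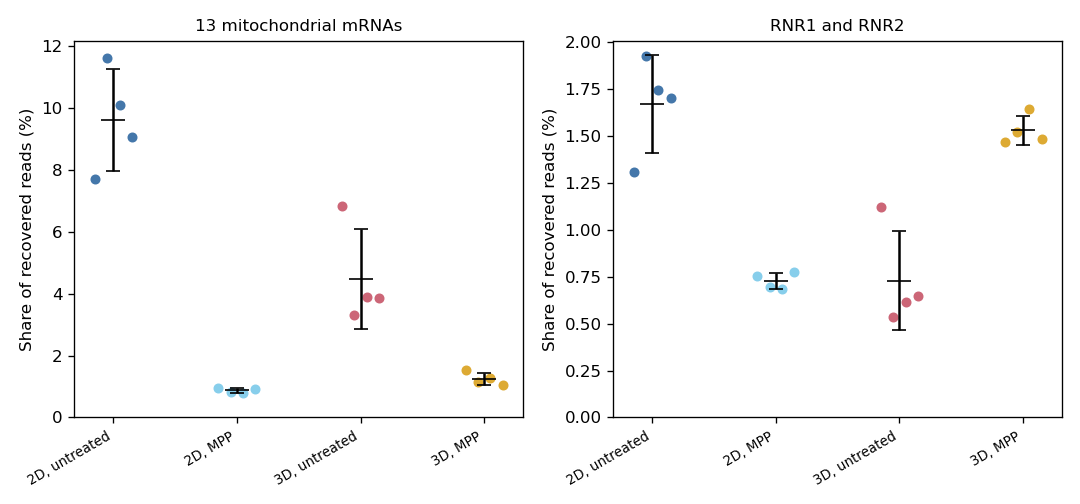
Points are the percent of each library's recovered reads on the 13 mitochondrially encoded mRNAs (left) and on the mitochondrial ribosomal RNAs RNR1 and RNR2 (right), by group, with the mean and SD (n = 4) in black. The mRNA share is 0.874% ± 0.0754 in MPP-treated 2D and 1.24% ± 0.207 in MPP-treated 3D, and the ribosomal RNA share is 0.727% ± 0.0432 and 1.53% ± 0.0775.

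The same toxin was then compared with no treatment in the scaffold. Of 17 glycolysis genes 0 rose and 16 fell (0 and 16 adjusted over the list alone, median log2 -1.63, camera adjusted p = 4.04e-28). Lactate dehydrogenase LDHA fell from 31768 ± 2085 to 4104 ± 217 (limma, log2 -2.95, SE 0.070, adjusted p = 2.12e-18). GPI fell from 39312 ± 4457 to 5755 ± 76.3 (limma, log2 -2.77, SE 0.068, adjusted p = 2.52e-18). Of 21 hypoxia-response genes 0 rose and 17 fell (0 and 19 adjusted over the list alone, median log2 -0.95, camera adjusted p = 1.22e-17). VEGFA fell from 38563 ± 5555 to 6992 ± 709, BNIP3 from 8602 ± 739 to 3303 ± 176 and NDRG1 from 7038 ± 918 to 3193 ± 241. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; median log2 -1.94, camera adjusted p = 8.52e-17, adjusted p = 0.0680 with an estimated correlation). COX3 fell from 155778 ± 47825 to 17409 ± 2439. The mRNA share of reads was 4.47% ± 1.61 untreated and 1.24% ± 0.207 with MPP.

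Of 30 integrated stress response genes 22 rose and 3 fell with MPP in 3D (23 and 4 adjusted over the list alone, median log2 0.63, camera adjusted p = 5.08e-11). ASNS rose from 3068 ± 63.2 to 9859.8 ± 253, the pseudokinase TRIB3 from 1415 ± 114 to 3921 ± 203 and the stress cytokine GDF15 from 6257 ± 717 to 38886 ± 12339.8. Of 22 cholesterol synthesis genes 17 rose and 0 fell (18 and 0 adjusted over the list alone, median log2 0.52, camera adjusted p = 1.34e-10). MSMO1 rose from 2564 ± 346 to 5033 ± 323. Of 30 cell cycle genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), and the list was not called (median log2 -0.057, camera adjusted p = 0.576). The median lay below 0, while the mean was 0.024 and the direction of the test upward. MPP-treated 3D replicate 3 stood apart from its group, with a median deviation of the list from its mean over the 16 libraries of 0.19, against -0.50 to -0.24 in the other 3. MKI67 fell from 2516 ± 195 to 1617 ± 519. Endoplasmic reticulum chaperone genes were not called either: 5 rose and 3 fell (5 and 4 adjusted over the list alone, median log2 0.024, camera adjusted p = 0.660).

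TH fell in 3D from 5585 ± 823 to 4241 ± 237 (limma, log2 -0.39, SE 0.11, adjusted p = 0.00661). SLC18A2 rose from 3129 ± 173 to 6007 ± 867 (limma, log2 0.93, SE 0.089, adjusted p = 3.90e-08). MAP2 was at 7649 ± 893 and 7216 ± 673 and was not called (limma, adjusted p = 0.576). Besides GDF15, the rises by the fixed rule were CALML3-AS1, LAMP3, TP73, INPP5D and KLHDC7B. TP73, a p53 family transcription factor, rose from 611 ± 159 to 3879 ± 735. CALML3-AS1, which cannot be told from its antisense partner without strand, rose from 14.1 ± 7.74 to 179 ± 84.7. ACTL8 fell from 812 ± 124 to 5.69 ± 6.20, the aquaglyceroporin AQP10 from 859.8 ± 208 to 22.6 ± 13.6 and erythropoietin (EPO), an oxygen-regulated hormone, from 205 ± 27.6 to 5.45 ± 3.90. ADCY8, FLT1 and TRNP also fell, with log2 changes of -5.30, -4.93 and -4.98. ADCY8 averaged 6.59 ± 5.27 with MPP in 3D, so its change depends on the value added before the logarithm.

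Other lists called in 3D were as follows. Of 14 immediate early genes 2 rose and 9 fell (2 and 9 adjusted over the list alone, median log2 -0.91, camera adjusted p = 4.64e-04). MPP-treated 3D replicate 1 stood apart, with a median deviation of the list of -0.0637 against -0.519 to -0.385 in the others. It still lay below the untreated 3D libraries, at 0.240 to 0.412. Of 7 genes of the metallothionein list 0 rose and 5 fell (0 and 5 adjusted over the list alone, median log2 -1.37, camera adjusted p = 0.00104, adjusted p = 0.0919 with an estimated correlation), SLC30A1, again named after its values were seen, among those that fell (limma, log2 -1.40, SE 0.14, adjusted p = 1.19e-07). Of 7 replication-dependent histone genes 0 rose and 4 fell (0 and 5 adjusted over the list alone, median log2 -1.68, camera adjusted p = 0.00686, adjusted p = 0.0414 with an estimated correlation). For this list MPP-treated 3D replicate 2 stood apart, with a median deviation of 0.270 against -1.01 to -0.476 in the others. The untreated 3D libraries lay at 0.696 to 1.13. The limit from poly-A selection given for histone genes in 2D holds here too. Of 12 retinoic acid response genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, median log2 0.28, camera adjusted p = 0.00191, adjusted p = 0.0566 with an estimated correlation). Of 22 p53 target and apoptosis genes 12 rose and 4 fell (12 and 4 adjusted over the list alone, median log2 0.34, camera adjusted p = 0.00468, adjusted p = 0.153 with an estimated correlation). Of 21 autophagy and lysosome genes 9 rose and 2 fell (10 and 2 adjusted over the list alone, median log2 0.20, camera adjusted p = 0.00965, adjusted p = 0.153 with an estimated correlation). Of 15 noradrenergic and sympathoadrenal genes 2 rose and 7 fell (2 and 8 adjusted over the list alone, median log2 -0.25, camera adjusted p = 0.00965, adjusted p = 0.421 with an estimated correlation). The call on noradrenergic genes was lost with quantile normalisation (0.0860), at an adjusted p of 0.00125 to 0.421 over all camera alternatives. Of 12 heat shock genes 0 rose and 6 fell (0 and 6 adjusted over the list alone, median log2 -0.25, camera adjusted p = 0.0185, adjusted p = 0.368 with an estimated correlation). The call on heat shock genes was lost with quantile normalisation (0.130), with edgeR (0.0524), without untreated 3D replicate 3 (0.0592), without MPP-treated 3D replicate 2 (0.0503) or without untreated 3D replicates 1 and 3 (0.0615), at an adjusted p of 0.00892 to 0.368 over all camera alternatives, and that on histone genes was lost with no filter (0.0535), at an adjusted p of 0.00144 to 0.0535 over all camera alternatives.

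In 3D, MPP changed 5879 genes by limma with Benjamini-Hochberg adjustment, 2882 upward and 2997 downward, 1113 of them by at least 2-fold. The upward share of 49.0% became 66.0% with equal library totals and 59.3% with equal nuclear totals.

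The difference between the MPP effects in 3D and 2D was tested as an interaction. Glycolysis genes responded lower in 3D than in 2D: of 17, 0 were higher and 16 lower (0 and 16 adjusted over the list alone, median log2 -1.38, camera adjusted p = 5.98e-32). Cell cycle genes responded higher in 3D: of 30, 28 were higher and 0 lower (30 and 0 adjusted over the list alone, median log2 1.30, camera adjusted p = 1.63e-31, adjusted p = 0.0390 with an estimated correlation). These genes were already lower in untreated 3D than in untreated 2D (median log2 -1.09). With MPP the median difference of 3D from 2D was 0.19. MPP-treated 3D replicate 3 was the highest of its group, with a list median of 0.19 against -0.50 to -0.24 in the other 3. For CDC6, a replication licensing factor, the mean was 1048 ± 75.2 and 244 ± 45.7 in 2D without and with MPP and 417 ± 38.3 and 605 ± 225 in 3D (limma, log2 2.59, SE 0.25, adjusted p = 1.19e-07). MCM6, of the replicative helicase, was at 2595 ± 178 and 1372 ± 65.6 in 2D and at 1293 ± 64.0 and 2163 ± 472 in 3D. Cholesterol synthesis genes responded lower in 3D: of 22, 0 were higher and 19 lower (0 and 19 adjusted over the list alone, median log2 -1.08, camera adjusted p = 3.36e-26). Hypoxia-response genes also responded lower in 3D: of 21, 0 were higher and 15 lower (0 and 16 adjusted over the list alone, median log2 -0.89, camera adjusted p = 1.75e-15). The log2 change of VEGFA was 0.79 in 2D and -2.46 in 3D.

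The mitochondrially encoded mRNAs fell less in 3D than in 2D: of 13, 13 were higher and 0 lower (13 and 0 adjusted over the list alone, median log2 1.62, camera adjusted p = 2.75e-16, adjusted p = 0.0751 with an estimated correlation). These mRNAs were already lower in untreated 3D than in untreated 2D (median log2 -1.21). With MPP the median difference of 3D from 2D was 0.27. RNR1, the small mitochondrial ribosomal RNA, was at 52830.4 ± 7519.9 and 35131 ± 3002 in 2D without and with MPP, and at 19260.4 ± 5156 and 93242 ± 7886 in 3D (limma, log2 2.89, SE 0.18, adjusted p = 1.48e-10). Endoplasmic reticulum chaperone genes responded higher in 3D: of 18, 12 were higher and 1 lower (13 and 3 adjusted over the list alone, median log2 0.51, camera adjusted p = 1.86e-06, adjusted p = 0.0689 with an estimated correlation). Immediate early genes responded lower in 3D: of 14, 0 were higher and 7 lower (0 and 8 adjusted over the list alone, median log2 -0.80, camera adjusted p = 5.06e-05). Of 30 integrated stress response genes 3 were higher and 11 lower (3 and 13 adjusted over the list alone, median log2 -0.18, camera adjusted p = 1.37e-05, adjusted p = 0.0751 with an estimated correlation). Of 73 cytosolic ribosomal protein genes 0 were higher and 1 lower (0 and 0 adjusted over the list alone, median log2 -0.21, camera adjusted p = 1.17e-04, adjusted p = 0.686 with an estimated correlation). The call on ribosomal protein genes was lost with quantile normalisation (0.521) or with array weights (0.0813), at an adjusted p of 1.09e-07 to 0.686 over all camera alternatives. Of 24 mature neuron and synapse genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone, median log2 -0.12, camera adjusted p = 0.0484, adjusted p = 0.386 with an estimated correlation). The call on mature neuron genes was lost with quantile normalisation (0.291), with a pseudocount of 5 (0.0520), with no filter (0.0564), with edgeR (0.0521), without untreated 2D replicate 2 (0.0622), without untreated 2D replicate 3 (0.0826), without untreated 2D replicate 4 (0.0516), without untreated 3D replicate 2 (0.0703), without untreated 3D replicate 3 (0.0905), without MPP-treated 2D replicate 4 (0.120), without MPP-treated 3D replicate 1 (0.105), without MPP-treated 3D replicate 2 (0.0728), with equal nuclear totals (0.141), with the GC and length correction (0.0804) or without untreated 3D replicates 1 and 3 (0.0628), at an adjusted p of 0.00733 to 0.386 over all camera alternatives.

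TH responded oppositely in the 2 cultures, 0.79 in 2D and -0.39 in 3D (limma, difference log2 -1.18, SE 0.15, adjusted p = 5.52e-06). SLC18A2 rose by 0.24 and 0.93 (limma, difference log2 0.69, SE 0.13, adjusted p = 4.61e-04). In MAP2 the difference was not called (limma, log2 -0.11, SE 0.15, adjusted p = 0.689). The largest differences by the fixed rule were ZNF90 and RNR1, higher in 3D, and ACTL8, CACNA1H and ADCY8, lower in 3D. CACNA1H, a T-type calcium channel subunit, was at 3.48 ± 1.98 and 25.4 ± 9.01 in 2D and at 818 ± 194 and 58.8 ± 11.8 in 3D.

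The interaction called 2602 genes by limma with Benjamini-Hochberg adjustment, 1189 higher and 1413 lower in 3D, 912 of them by at least 2-fold. The higher share of 45.7% became 66.9% with equal nuclear totals. Across the 16984 genes the MPP changes in 2D and 3D, which share no libraries, correlated at Pearson r = 0.394, and 67.6% had the same sign. In both cultures 1375 genes rose and 1327 fell, against 509 and 506 for independent lists, and 334 were called in opposite directions against 1016.

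**Figure D4:**
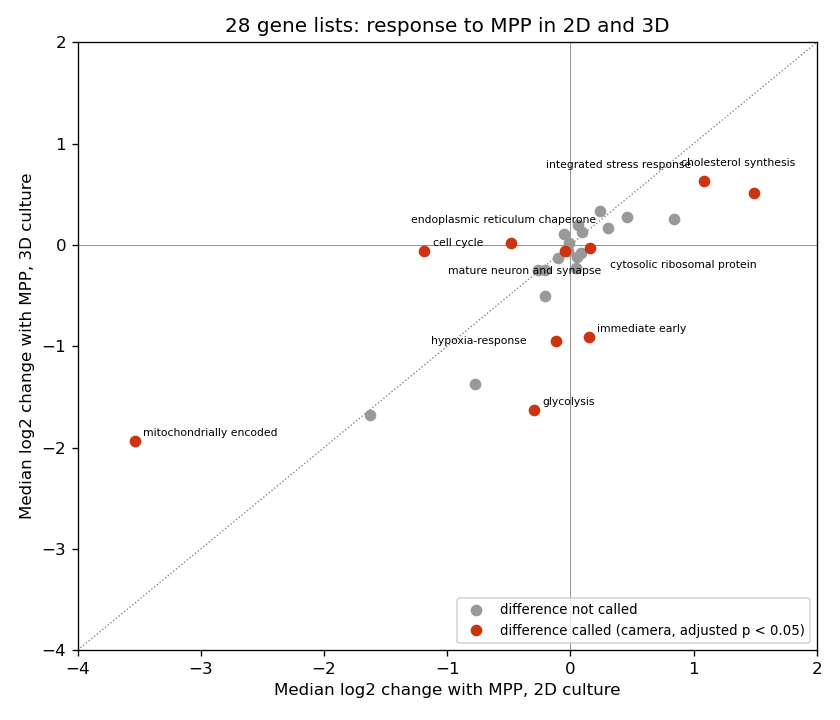
Each point is 1 of the 28 gene lists, placed by its median log2 change with MPP in 2D (x) and in 3D (y), with the line of equality dotted. Red points are the 10 lists whose response differed between cultures by camera at the preset correlation, of which 5 held with an estimated one, among them glycolysis genes at -0.29 and -1.63 and cell cycle genes at -1.19 and -0.057.

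The last comparison set 3D against 2D among MPP-treated cultures. TH was 595 ± 91.0 in 2D and 4241 ± 237 in 3D (limma, log2 2.84, SE 0.11, adjusted p = 4.18e-15). SLC18A2 was 1153 ± 68.5 and 6007 ± 867 (limma, log2 2.37, SE 0.089, adjusted p = 4.49e-15). MAP2 was lower in 3D, at 7216 ± 673 against 10226 ± 1719.6, and MKI67 was not called (limma, adjusted p = 0.452). Cholesterol synthesis genes were lower in 3D: of 22, 0 were higher and 21 lower (0 and 21 adjusted over the list alone, median log2 -0.87, camera adjusted p = 2.82e-19). HMGCS1 was at 44966 ± 2007 in 2D and 15099 ± 1699 in 3D, and STARD4, a sterol carrier, at 13519.9 ± 906 and 3029 ± 117.

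Of 24 mature neuron and synapse genes 2 were higher and 19 lower in 3D with MPP (2 and 20 adjusted over the list alone, median log2 -0.55, camera adjusted p = 1.79e-11). The RNA-binding protein gene ELAVL4 was at 21222 ± 2338 in 2D and 3667 ± 873 in 3D, and neurofilament NEFM at 6145 ± 133 and 2858 ± 209. Of 18 endoplasmic reticulum chaperone genes 16 were higher and 0 lower (17 and 0 adjusted over the list alone, median log2 0.55, camera adjusted p = 1.87e-11). HSPA5 was at 6702 ± 419 and 15641 ± 2442 and PDIA4 at 6223 ± 271 and 11675 ± 876. Of 73 cytosolic ribosomal protein genes 51 were higher and 0 lower (52 and 0 adjusted over the list alone, median log2 0.35, camera adjusted p = 1.12e-12, adjusted p = 0.415 with an estimated correlation). Of 30 integrated stress response genes 22 were higher and 2 lower (22 and 2 adjusted over the list alone, median log2 0.45, camera adjusted p = 3.80e-10). STC2 was at 272 ± 17.1 and 1701 ± 262. Of 17 mesenchymal neuroblastoma-state markers 4 were higher and 10 lower (4 and 10 adjusted over the list alone, median log2 -0.77, camera adjusted p = 0.00767). Of 14 inflammation and interferon genes 0 were higher and 8 lower (0 and 8 adjusted over the list alone, median log2 -0.65, camera adjusted p = 0.00767).

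TPSAB1, TPSB2, TPSD1 and INSM1 had 0 reads in MPP-treated 2D. Against the same floor their counts in 3D were at least 1192-fold, 1106-fold, 241-fold and 166-fold higher. MAF had 2 reads and was 171-fold higher, with a 95% exact Poisson interval of 47.4 to 1413. GABRP, IFI44, ARHGAP42, ASS1, SLC6A2 and VCAN were the lowest in 3D, with log2 differences from -4.60 for GABRP to -3.44 for VCAN. VCAN, a matrix proteoglycan, was at 9067 ± 2477 in 2D and 831 ± 207 in 3D.

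Further lists called with MPP were hypoxia-response genes, of which 10 were higher and 2 lower (11 and 4 adjusted over the list alone, median log2 0.26, camera adjusted p = 0.00767, adjusted p = 0.297 with an estimated correlation). They also included retinoic acid response genes, of which 2 were higher and 7 lower (2 and 7 adjusted over the list alone, median log2 -0.33, camera adjusted p = 0.00767, adjusted p = 0.101 with an estimated correlation). Among noradrenergic and sympathoadrenal genes 3 were higher and 9 lower (3 and 9 adjusted over the list alone, median log2 -0.46, camera adjusted p = 0.00979, adjusted p = 0.50 with an estimated correlation). Among cell cycle genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone, median log2 0.19, camera adjusted p = 0.00979, adjusted p = 0.595 with an estimated correlation). The call on cell cycle genes was lost without MPP-treated 3D replicate 3 (0.212), at an adjusted p of 3.62e-05 to 0.595 over all camera alternatives, and without that replicate the median was 0.026. Among glycolysis genes 0 were higher and 8 lower (1 and 8 adjusted over the list alone, median log2 -0.18, camera adjusted p = 0.0228, adjusted p = 0.50 with an estimated correlation). The call on glycolysis genes was lost with edgeR (0.114) or without MPP-treated 3D replicate 1 (0.0516), at an adjusted p of 0.0125 to 0.50 over all camera alternatives. Among mitochondrially encoded mRNAs 6 were higher and 0 lower (6 and 0 adjusted over the list alone, median log2 0.27, camera adjusted p = 0.0255, adjusted p = 0.595 with an estimated correlation). The call on mitochondrially encoded genes was lost with array weights (0.0512), with robust empirical Bayes (0.0838), with edgeR (0.0744), without MPP-treated 2D replicate 3 (0.0580), without MPP-treated 3D replicate 1 (0.0907) or with the GC and length correction (0.0923), at an adjusted p of 0.00258 to 0.595 over all camera alternatives.

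With MPP, 6615 genes differed between 3D and 2D by limma with Benjamini-Hochberg adjustment, 3232 higher and 3383 lower in 3D, 1373 of them by at least 2-fold. The culture differences with and without MPP, which share no libraries, correlated across genes at Pearson r = 0.626. In both, 1879 genes were higher and 2143 lower in 3D, against 748 and 776 for independent lists, and 357 were called in opposite directions against 1525.

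**Figure D5:**
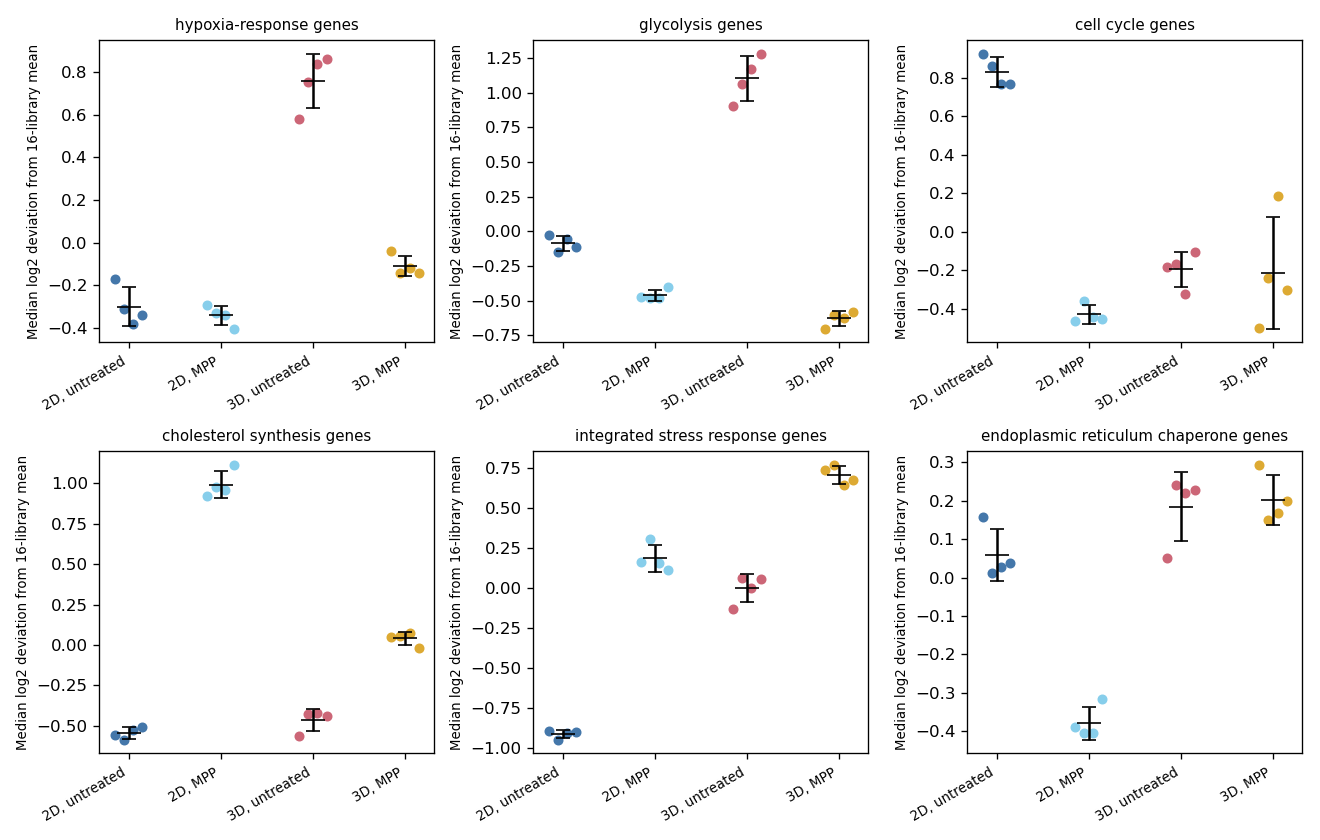
Points are the median over 6 of the gene lists, for each library, of the log2 deviation of each member from its mean over the 16 libraries, by group, with the mean and SD (n = 4) in black. Hypoxia-response and glycolysis genes are highest in untreated 3D, cell cycle genes in untreated 2D and cholesterol synthesis genes in MPP-treated 2D.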

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

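The tests of library scaling, of mitochondrial ribosomal RNA, of GC content and transcript length, of mast cells, of reads shared between tryptases, of genes picked by group means and of shuffled residuals were chosen after their results were seen; the other tests here were written first.

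Among the assignments of these 16 libraries to groups that were tried, the real one gave the most genes in every comparison. Only this rank is read, and with 35 splits it cannot go below 1 in 35. A split that mixes differing groups widens the spread within them, which lowers its count. Shuffled residuals likewise hold any interaction as spread. The real grouping was the only 1 of 35 splits to give as many genes in each of the 4 comparisons of groups: 5866 genes against at most 0 in another split for MPP in 2D, 5879 against 104 for MPP in 3D, 7830 against 1 for untreated 3D against 2D and 6615 against 0 for 3D against 2D with MPP. For the difference of the MPP effects, residuals of a fit of both effects without their interaction were shuffled over the libraries; 1 of 100 draws, the real one, gave 2602 genes, and the highest other gave 0. Redrawing the culture labels within each treatment gave at most 1794 genes in the other draws, but it moves the culture effect as well, so nothing about the difference is taken from it. The labels do not show that the libraries are separate cultures, so differences between single cultures are not covered.

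Single libraries lay far from the other 3 of their group in 18 of 293 groups of values tested by Dixon's ratio, and chance gives about 1 in 20 groups, or 14.7 here. Most of the 18 lay in untreated 3D, which enters the comparisons of MPP in 3D, of untreated culture and of the difference. Genes with every value of a group under 10 were not tested. The mitochondrial mRNA share of reads was 6.84% in untreated 3D replicate 1 against 3.30 to 3.89%. The percent of reads on the 10 most abundant genes was 9.52 in untreated 3D replicate 1 against 7.73 to 8.03, and 6.87 in MPP-treated 3D replicate 1 against 6.62 to 6.64. Normalised counts of single genes also stood apart. ASNS was 3162 in untreated 3D replicate 3 against 3028 to 3044, CACNA1H was 1107 in untreated 3D replicate 3 against 698 to 752, and CYTB was 198103 in untreated 3D replicate 1 against 92014 to 107710.0. DHCR7 was 10228 in untreated 3D replicate 3 against 9135 to 9306, DHCR7 was 25506 in MPP-treated 2D replicate 4 against 23332 to 23604, and ELAVL4 was 23167 in untreated 2D replicate 1 against 20899.9 to 21137. MAP2 was 12783 in MPP-treated 2D replicate 4 against 9106 to 9648, MCM6 was 1198 in untreated 3D replicate 4 against 1313 to 1335, and MSMO1 was 11716 in MPP-treated 2D replicate 4 against 9951 to 10182. SLC7A11 was 39.2 in untreated 2D replicate 4 against 4.11 to 6.89, TRHDE was 35.2 in untreated 3D replicate 2 against 2.98 to 8.45, and TRNP was 2324 in untreated 3D replicate 1 against 1417 to 1566. VCAN was 12754 in MPP-treated 2D replicate 4 against 7453 to 8205, VEGFA was 46888 in untreated 3D replicate 1 against 35444 to 35993, and ZNF90 was 22.4 in untreated 3D replicate 4 against 46.5 to 47.7.

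The effect of MPP differed between 3D and 2D, by the interaction test with camera at the preset correlation, in 10 lists, of which 5 held with an estimated correlation: glycolysis genes, cell cycle genes, cholesterol synthesis genes, hypoxia-response genes and immediate early genes. Median differences of the 10, 3D minus 2D on the log2 scale, were glycolysis genes (-1.38), cell cycle genes (1.30), cholesterol synthesis genes (-1.08), mitochondrially encoded genes (1.62), hypoxia-response genes (-0.89), endoplasmic reticulum chaperone genes (0.51), integrated stress response genes (-0.18), immediate early genes (-0.80), cytosolic ribosomal protein genes (-0.21) and mature neuron and synapse genes (-0.12).

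By limma the interaction was also called for 42 of the 48 genes named for MPP or its difference, many of which were picked for large changes. On the log2 scale, 3D minus 2D, the difference was positive for TRIB3 (0.37), ND3 (0.66), SLC18A2 (0.69), HSPA5 (0.78), CALR (0.92), MKI67 (1.08), PCNA (1.13), TPX2 (1.19), CYTB (1.46), TRNP (1.59), MCM6 (1.64), COX1 (1.82), COX3 (1.92), LAMP3 (1.97), COX2 (2.22), TP73 (2.41), CDC6 (2.59), RNR1 (2.89) and ZNF90 (3.03). It was negative for ACTL8 (-6.52), CACNA1H (-6.34), ADCY8 (-5.78), EPO (-5.64), FLT1 (-5.28), PRDM16 (-5.06), AQP10 (-3.97), FUT3 (-3.28), SLC7A11 (-3.26), VEGFA (-3.25), LIPG (-2.91), GOLGA6C (-2.70), GPI (-2.51), ALDOA (-2.01), HMGCS1 (-1.89), NDRG1 (-1.80), LDHA (-1.72), C6orf223 (-1.51), DHCR7 (-1.48), SLC7A5 (-1.40), TH (-1.18), BNIP3 (-1.14) and MSMO1 (-1.10). FLT1 had 0 reads in untreated 2D, so its fitted difference depends on the value added before the logarithm. ACTL8, CACNA1H, EPO, FUT3 and GOLGA6C averaged 4.51, 3.48, 2.01, 4.37 and 2.10 in untreated 2D, so their differences depend on that value too. In MPP-treated 3D, ADCY8, ACTL8 and EPO averaged 6.59, 5.69 and 5.45, and the difference of ADCY8 also depends on the added value.

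The fall of the mitochondrially encoded mRNAs with MPP was weighed against library scaling and against a loss of all mitochondrial transcripts alike. Over 4 other scalings and both cultures the median change of the 13 mRNAs was never closer to 0 than -1.75 on the log2 scale, which argues against scaling as the whole source. In 3D, RNR1 rose by 2.31 and RNR2 by 0.86 with MPP, and the nearer of them lay 2.80 above the median mRNA change, which argues against an equal loss of every mitochondrial transcript. In 2D both fell, with log2 changes of -0.58 for RNR1 and -1.38 for RNR2. A change in the making or decay of the mRNAs, and a change in how mitochondrial ribosomal RNA enters poly-A libraries, stay open and untested.

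The fall of hypoxia-response and glycolysis genes with MPP in 3D starts from the untreated 3D libraries in which they were high. When those 4 libraries were split, the culture and MPP comparisons shared none of them. The smallest absolute median of the hypoxia list over the 6 splits was 0.888. In the 4 libraries the median deviation of the list lay close together, at 0.581 to 0.863, so little else could result. The splits speak only to scatter between these libraries. A condition common to all 4 stays in every split and is not addressed. After a correction for GC content and transcript length, known for all 21 hypoxia and 17 glycolysis genes tested, the hypoxia median with MPP in 3D was -0.926 against -0.95 before. A second list of 17 oxygen-regulated genes outside the fixed lists had medians of 1.23 in untreated 3D against 2D, -1.04 with MPP in 3D and -0.15 with MPP in 2D, with 14 members falling in 3D. This is consistent with a hypothesis that oxygen-regulated genes as a class were raised in the scaffold and lowered by MPP there, with less oxygen use as a candidate explanation that stays untested, since oxygen was not measured and handling differs with culture.

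Genes near 0 in 2D and high in 3D were weighed against mast cells, a few outlying libraries and shared reads. HDC, the only 1 of CPA3, HDC, MS4A2 and FCER1A in the table, reached 0.0777% of the tryptase sum of 3444 in untreated 3D, which argues against mast cells; KIT, also expressed in neural crest cells, was at 278 in untreated 2D and 228 in untreated 3D. The lowest count of FLT1, TPSAB1, TPSB2 or CBFA2T3 in any untreated 3D library was 617 reads, an outcome nearly fixed by the naming rule, but among all 20 genes picked by group means alone (under 1 in untreated 2D, 50 or more in untreated 3D) the lowest value of any untreated 3D library was 48.9% of its gene's group mean, which argues against a few libraries carrying the mean. The 4 tryptase genes together had 0 reads in untreated 2D and 10735 in untreated 3D, so an exchange of reads between paralogs does not account for the difference, though it can move reads among them within 3D. Activation of these genes by the scaffold, selection of a subpopulation and other handling stay open and untested.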

How the results depend on the processing

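Equal nuclear totals, the GC and length correction and the fits without untreated 3D replicates 1 and 3 were chosen after seeing the data; the other alternatives were planned. In the order MPP in 2D, MPP in 3D, 3D against 2D untreated, the same with MPP, and the difference of effects, the gene counts stayed within 1.5 times the main ones under every alternative but a 2-fold minimum, which keeps fewer genes by construction: 1084, 1113, 2106, 1373 and 912. On the recovered reads edgeR called 5876, 5815, 7722, 6677 and 2571 genes and DESeq2 6311, 6171, 8060, 7016 and 3041. Without untreated 3D replicates 1 and 3 the counts were 4983 for MPP in 3D, 6609 for untreated culture and 2480 for the difference. Leaving out 1 library gave 4771 to 5510, 5247 to 5717, 7017 to 7626, 5683 to 6293 and 2142 to 2912 genes, and 15 to 16, 12 to 14, 8 to 10, 12 to 14 and 9 to 11 lists. With an estimated correlation camera called 7, 6, 3, 6 and 5 lists. With fry, which does not compare a list with other genes, 20, 21 and 20 lists were called for MPP in 3D and culture without and with MPP. For 3D against 2D with MPP, dopamine neuron and catecholamine genes had a median of -0.0993, a mean of 0.14, a downward camera direction that was not called and an upward fry direction (fry adjusted p = 0.0216), and the cause was not tested. The correlation of MPP effects between cultures moved from 0.394 to 0.325 with no filter and 0.441 for a mean of 50 or more, where fewer low genes are included, and was 0.364 to 0.417 with 1 library left out. Among named genes, the call was unchanged in 2956 values and lost in 8, in SLC18A2 with MPP in 2D alone. Among lists it was unchanged in 3475, lost in 84 and gained in 75. No named gene reversed direction with a call, and reversals between uncalled values were not counted. Replicate numbers were not taken to pair the samples, though pairing was not tested. Correlations of same-numbered deviations ran from -0.115 to 0.0896, and 1, 2, 0 and 3 of 4 samples correlated best with their own number. For 3D against 2D with MPP, where 3 did so, these correlations were 0.0112 to 0.0822. With the replicate block the gene counts were 5675, 5706, 7634, 6451 and 2436 with limma and 5681, 5605, 7480, 6461 and 2403 with edgeR. The block also ended the camera call on mature neuron genes for the difference (adjusted p = 0.0523 with limma, 0.0605 with edgeR). With edgeR and the block, camera lost immediate early genes in untreated 3D (adjusted p = 0.0521). That fit called NRF2 genes with MPP in 2D (camera adjusted p = 0.0449). Genes near the floor are limited by depth, the untreated 3D libraries being the shallowest.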

Other observations

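DDC, SLC18A1, MAOA, MAOB, DLK1, EPAS1 and CHGB were chosen after their values were seen. Within the catecholamine genes the members moved apart. DDC, the enzyme that makes dopamine from L-DOPA, rose from 2745 ± 154 to 14143 ± 567 between untreated 2D and 3D and fell to 2851 ± 602 with MPP in 3D (limma, log2 -2.33, SE 0.10, adjusted p = 5.47e-14). SLC18A1, the vesicular monoamine transporter of endocrine cells, went from 2433 ± 148 to 32645 ± 1593 and with MPP in 3D to 4945 ± 563 (limma, log2 -2.73, SE 0.082, adjusted p = 6.84e-17), whereas SLC18A2 rose there. The degrading enzymes MAOA and MAOB fell in untreated 3D, with log2 changes of -1.27 and -0.75. As a list, the 16 dopamine neuron and catecholamine genes had 6 higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.548) in untreated 3D, 4 higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.860) with MPP in 2D and 3 higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.225) with MPP in 3D. With edgeR camera called this list in untreated 3D (median log2 0.17, adjusted p = 0.00520), with MPP in 3D (median log2 -0.069, adjusted p = 0.0106) and for the difference of the MPP effects (median log2 -0.077, adjusted p = 0.00294), at adjusted p of 0.00284 to 0.700, 0.00926 to 0.408 and 0.00209 to 0.287 over all camera alternatives, and the cause was not tested. DLK1, a Notch-like ligand of sympathoadrenal cells, rose from 38806 ± 3817 to 658337 ± 37413 (limma, log2 4.09, SE 0.086, adjusted p = 1.01e-19), and EPAS1, the hypoxia-inducible factor 2 alpha, from 5531 ± 237 to 25004 ± 1397 (limma, log2 2.18, SE 0.094, adjusted p = 2.10e-14). CHGB, a granule protein of neuroendocrine cells, fell from 207877 ± 8159 to 43184 ± 4539, and the 15 noradrenergic and sympathoadrenal genes had 2 higher and 7 lower (2 and 8 adjusted over the list alone; camera adjusted p = 0.0260), adjusted p = 0.532 with an estimated correlation.

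Several groups tied to complex I, to Parkinson's disease or to neurons were not called by camera with the main settings in any of the 5 comparisons. Of 35 nuclear genes of complex I, 4 rose and 6 fell (3 and 6 adjusted over the list alone) with MPP in 2D and 2 rose and 9 fell (2 and 9 adjusted over the list alone) in 3D. Of 21 tricarboxylic acid cycle genes 4 rose and 4 fell (4 and 4 adjusted over the list alone) in 2D and 6 rose and 2 fell (7 and 3 adjusted over the list alone) in 3D. Of 15 familial Parkinson disease genes 3 rose and 1 fell (3 and 1 adjusted over the list alone) in 2D and 4 rose and 3 fell (4 and 3 adjusted over the list alone) in 3D. Of 19 NRF2 antioxidant genes 8 rose and 3 fell (9 and 4 adjusted over the list alone) in 2D and 7 rose and 4 fell (7 and 6 adjusted over the list alone) in 3D. Of 11 stem and progenitor markers 1 rose and 3 fell (1 and 3 adjusted over the list alone) in 2D and 1 rose and 7 fell (2 and 8 adjusted over the list alone) in 3D. Of 26 extracellular matrix and adhesion genes 8 rose and 10 fell (9 and 10 adjusted over the list alone) in untreated 3D against 2D. Of 13 genes of other neurotransmitter types 3 rose and 5 fell (3 and 5 adjusted over the list alone) in untreated 3D. Their camera adjusted p with MPP in 2D and 3D were 0.218 and 0.217 for complex I, 0.860 and 0.0774 for the tricarboxylic acid cycle, 0.971 and 0.601 for Parkinson disease genes, 0.0916 and 0.205 for NRF2 genes, and 0.223 and 0.0926 for stem markers. For Parkinson disease genes in 2D the median was below 0 and the direction of the test upward. In untreated 3D against 2D they were 0.680 for matrix genes and 0.445 for other neurotransmitter types. With camera, some alternatives called 3 of these groups. Tricarboxylic acid cycle genes were called with MPP in 3D with equal library totals (0.0191) or with equal nuclear totals (0.0247), at an adjusted p of 0.0191 to 0.408 over all camera alternatives, and for the difference of the MPP effects with no filter (0.0425), without MPP-treated 3D replicate 2 (0.0377) or with equal nuclear totals (0.00819), at an adjusted p of 0.00819 to 0.379 over all camera alternatives. Matrix genes were called for 3D against 2D with MPP with equal library totals (0.0477), with quantile normalisation (0.0455), with no filter (0.0481), with only the groups compared (0.0445), without MPP-treated 2D replicate 3 (0.0342), without MPP-treated 3D replicate 1 (0.0450), without MPP-treated 3D replicate 4 (0.0409) or with equal nuclear totals (0.0481), at an adjusted p of 0.0342 to 0.50 over all camera alternatives. NRF2 genes were called with MPP in 2D without untreated 2D replicate 1 (0.0479), at an adjusted p of 0.0449 to 0.419 over all camera alternatives. The immediate early genes had 6 higher and 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.0440) in untreated 3D, adjusted p = 0.137 with an estimated correlation. That call was lost with quantile normalisation (0.0639), without untreated 2D replicate 3 (0.0510), without untreated 2D replicate 4 (0.0626), without untreated 3D replicate 2 (0.0694), without untreated 3D replicate 3 (0.0587) or with the GC and length correction (0.154), at an adjusted p of 0.0155 to 0.154 over all camera alternatives.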
